A study of Salmo salar with 18 samples.

How the data were processed

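Liver RNA of 18 Atlantic salmon, 9 per diet, was hybridised to 18 arrays of 2 colours. Per the labels' protocols, the RNA was extracted with TRIzol, re-extracted with phenol and chloroform because of low purity readings, treated with DNase and purified on columns, and amplified antisense RNA was labelled with Cy5 for each fish and with Cy3 for the pool of all fish. No dyes were swapped, so a dye effect shared by all arrays cancels in the difference between the diets. Groups and fish numbers were taken from the labels.

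The scanner files hold the spot and background intensity of both channels, made by the authors with ImaGene version 9.0, per the file headers. These intensities are not normalized, and their values stop at 1 below and at the scanner's limit above. Per the file headers the first image is Cy3 and the second Cy5. The files also carry flags for spots marked by hand, empty or poor, and a list of reasons for a poor spot. A table of the whole series holds log2 ratios deposited by the authors for 43689 features. Set against the scanner values of the same array, these followed log2 of background-subtracted Cy5 over Cy3 with a slope of 0.952 to 1.03 and a correlation across features of 0.929 to 0.992, which settled their scale and direction. The medians of the deposited log2 columns lay between -0.11 and -0.04, and how they were normalized and centred is not given in the sources used here. They held 16102 to 19219 values per array and 0 values at flagged spots. They served as an alternative only. Columns of per-sample values that belonged to no sample numbered 0. The highest share of identical Cy5 values between any pair of arrays was 0.210%, so no array was a copy of another.

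Background was corrected with normexp and an offset of 50 in limma version 3.58.1 under R version 4.3.3, and each array was normalized by loess, with control spots (1531 of 45220 spots) and flagged spots at weight 0. Spots flagged by hand or as poor for any reason other than saturation were set missing (5.25% to 12.6% of an array), and saturated spots were kept. A feature was tested if the file's own empty-spot flag called its Cy5 signal above background on at least 9 of the 18 arrays, which 38903 were. Features also needed at least 2 values per diet, a rule set after the files had been read, which left 275 unfitted and 38628 tested. Each feature had 1 spot on an array. Diets were compared with lmFit and eBayes on the log2 ratios, camelina minus FO, in a 2-sided moderated test with Benjamini-Hochberg adjustment over all features tested and a threshold of 0.05. Where only some arrays measured a feature above background, their number is given. Fold changes are on the scale with the offset, which shrinks the differences of dim features.

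The moderated test was tried on simulated normalized log2 ratios with the spread and missing spots of the real features. In these, 200 of 38628 features were changed between the camelina diet and the fish oil diet. At a threshold of 0.05 it recovered 34.8% of features changed 1.5-fold and 69.6% of those changed 2-fold. It recovered 95.6% of those changed 3-fold and 97.2% of those changed 4-fold. The sign was right in 100%, with 5 false calls on average. Background correction, loess and the filter on dim features were not tried. Features were drawn independently, without slide or array structure, so recovery on the real arrays may differ. Each size of change was given to an equal number of features. The adjusted threshold is easier to pass when many features change strongly, so these shares hold for that mix only. On the real arrays 7 features passed, and with few strong changes recovery of 1.5-fold and 2-fold changes would be lower. The shares therefore do not tell how many such changes were missed.

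The test, the threshold, the filter on dim features, gene lists and the rule for named genes were fixed before the data were examined. The lists could not be used, because the files do not pair features with genes and the reference table (assembly Ssal_v3.1) matched 0 of 409 records. The rule for named genes took, among genes past the threshold, those with the largest change in each direction, filled up by smallest p where fewer than 10 features passed, and further list members and preset genes. It was applied to feature identifiers, limited to 2 that rose and 2 that fell. The parts on lists and preset genes had nothing to work on. How the other parts combine, passing features by size first and then the rest by smallest p, was settled after values had been seen.

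The number of features at unadjusted p-values, the distance between the diet means and the comparison of each fish with the means of the other fish were added after the data had been examined. The distance is the squared difference of the means summed over tested features with no missing value on any array. Its p-value is the share of all splits of the fish with a distance at least as large, which is 2-sided by construction. Image names in the file headers place the arrays on 5 slides, each with both diets: 1 FO and 2 camelina arrays on slide 1, 2 and 2 on slide 2, 3 and 1 on slide 3, 2 and 2 on slide 4, and 1 and 2 on slide 5. Differences within slides, with slide as a block and with diets exchanged only within slides were therefore computed. The header day separates slide 3 from the others and was used as a further block. Same-numbered fish of the 2 diets are different animals.

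Alternatives were other background corrections, normalizations within and between arrays, the Cy5 channel alone, other filters on dim features, the deposited ratios, blocks for slide, day and fish number, array weights, trended and robust eBayes, a looser threshold, rank products computed directly with 100 permutations, and leaving out each fish in turn. Some were added after the data had been examined: a filter on negative-control spots, keeping flagged spots, a limit on missing arrays, and leaving out 3 arrays with many features high in 1 fish alone. The alternative without background subtraction also left out the offset. Other splits of the fish were judged from 100 splits, the real one included.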

Results

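The series measured liver transcripts of juvenile Atlantic salmon (Salmo salar) on 18 arrays of 2 colours. A fish oil diet, labelled FO, had been fed to 9 fish, and 9 had been fed a diet labelled 100COSEFM10CM, called the camelina diet here after the series title, which speaks of diets with camelina products (camelina is an oilseed plant). The comparison is between whole diets, so no difference can be assigned to camelina or to another single ingredient. All livers were taken at week 16 of feeding. Per the series description, 3 fish came from each of 3 tanks per diet. The labels do not say which fish shared a tank, so every p-value over fish treats the fish as independent and is too small if tank-mates resemble each other. The RNA of each fish, in Cy5, was hybridised against a pool of the RNA of all 18 fish, in Cy3, so that a log2 ratio of 0 means the level of the pool. Each array held 43689 test features. By the empty-spot flag, Cy5 was above background on 60.4% to 92.7% of them. The median was 89.5% over the FO arrays and 85.1% over the camelina arrays. This flag is lenient: 38903 features passed it on at least 9 arrays. On as many arrays, 22840 exceeded the 95th percentile of the negative-control spots in Cy5. Saturated Cy5 spots made up 1.80% to 2.65% of an array. The number of arrays, 9 per diet, limits the precision of the diet means.

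The comparison that the design implies is camelina diet against fish oil diet, which asks how the liver transcriptome differed after 16 weeks on the camelina diet. The files used here do not pair features with gene names: 0 of the test features had a gene name, a top hit or a description, and of the 409 features named by a GenBank or RefSeq record 0 matched the reference gene table. Features are therefore given by their position identifiers, and nothing is said of what the transcripts do.

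Few single features were called different between the livers of the 2 diets. Of 38628 features tested, 7 differed at a limma adjusted p under 0.05. Of these, 1 was higher on the camelina diet and 6 were lower, a balance that single fish changed: 13 were higher and 10 lower without FO fish 5, 8 and 14 without camelina fish 9, and 3 and 3 without camelina fish 2. With normexp background correction and an offset of 50, the falls lay between 1.77-fold and 4.18-fold. In 5 of the 7 features the values of the 9 FO and the 9 camelina fish, or of those with a value, did not overlap. For a feature with 9 values per diet chance leaves no overlap in 0.00411% of splits, but these features had been picked for their small p, and 2 of the 5 had 8 FO values. At a looser adjusted p under 0.10, 14 features passed, 3 higher and 11 lower on the camelina diet.

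Feature C186R092 rose on the camelina diet. Its log2 ratio was -0.35 ± 0.15 (SD, n = 9) in FO fish and 0.17 ± 0.11 (SD, n = 9) in camelina fish. The difference was 0.52 (SE 0.079, 95% interval 0.36 to 0.69), or 1.43-fold, with a limma adjusted p of 0.0466. All 9 camelina fish lay above all 9 FO fish, and the difference was positive on each of the 5 slides, from 0.35 to 0.72. Feature C230R050 had a larger difference that did not pass, at a limma adjusted p of 0.0502. It averaged -0.37 ± 0.39 (SD, n = 9) in FO fish and 0.73 ± 0.43 (SD, n = 9) in camelina fish, a difference of 1.10 (SE 0.19), and within slides it differed by 0.47 to 1.53.

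Feature C113R049 had the largest fall among the 7 features that passed. Its log2 ratio was 0.25 ± 0.90 (SD, n = 9) in FO fish and -1.81 ± 0.61 (SD, n = 9) in camelina fish. The difference was -2.06 (SE 0.33, 95% interval -2.76 to -1.37), or 4.18-fold, with a limma adjusted p of 0.047. Its size depended on the background step and the offset. Without background subtraction and offset the difference was -5.85 and did not pass, at a limma adjusted p of 0.438. With normexp and an offset of 10 it was -2.37 and did not pass, at a limma adjusted p of 0.0588. Over its alternatives the limma adjusted p lay between 0.00775 and 0.438. This feature was above background in Cy5 on only 5 of 9 FO arrays and 5 of 9 camelina arrays, and the values of the diets overlapped. Feature C079R110 fell from 0.78 ± 0.29 (SD, n = 9) to -0.33 ± 0.38 (SD, n = 9). Its difference was -1.11 (SE 0.16), or 2.16-fold, with a limma adjusted p of 0.0312, the smallest of all features tested. It was above background on 8 FO arrays and on 5 camelina arrays, and every FO fish lay above every camelina fish. Within slides C113R049 differed by -3.09 to -1.28 and C079R110 by -1.35 to -0.65. All 7 features that passed had the same direction on every slide that measured both diets, which for 5 of them follows from the lack of overlap and does not show independence from slide. With single fish left out, C186R092 passed in 6 of 18 runs, C113R049 in 5, C079R110 in 10 and C230R050 in 3.

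**Figure D1:**
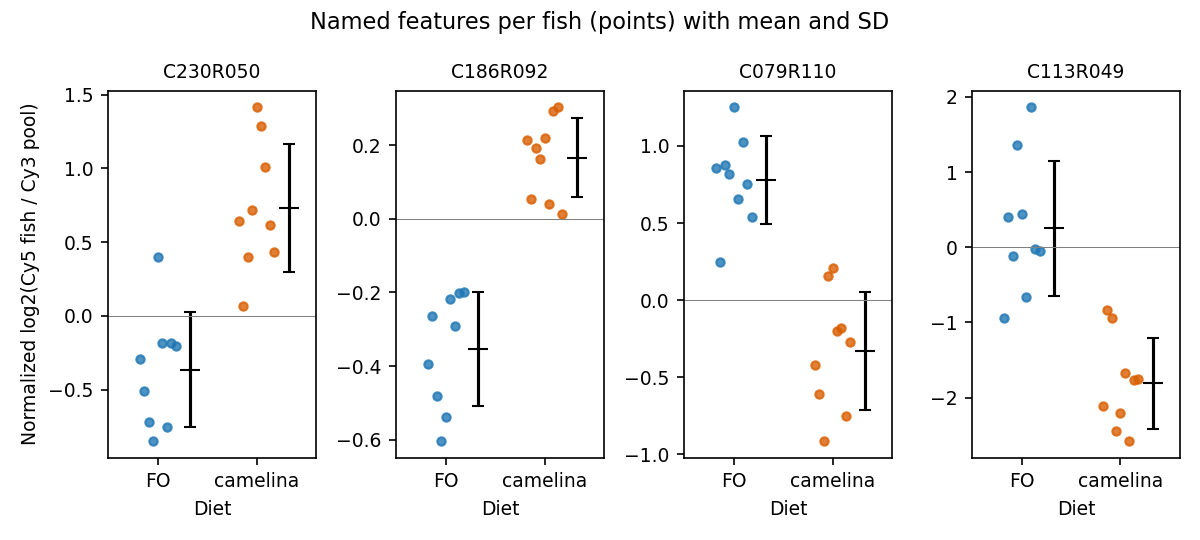
Normalized log2 ratio (fish over pool) of the 4 named features, one point per fish for the FO diet and the camelina diet, with the mean and SD of the 9 fish of each diet beside the points; each panel has its own vertical axis. The diets do not overlap for C186R092 and C079R110, and they do for C230R050, which did not pass the adjusted threshold, and C113R049.

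Which single features passed depended on the fish and on the model. With slide as a fixed block 1 feature passed, which was higher on the camelina diet and none of the 7, and the 4 named features had limma adjusted p-values of 0.0936 (C186R092), 0.0636 (C230R050), 0.149 (C113R049) and 0.0805 (C079R110), in the same directions. Over all alternatives but the removal of single fish, the adjusted p of these 4 features lay between 0.00775 and 0.721. No feature passed in limma with the header day as a block, without background subtraction and offset, or with Cy5 alone. None passed with a filter of 14 arrays, which tested 5 of the 7, or with the deposited ratios, which tested 6. At an unadjusted limma p under 0.05 these settings had 2032 features (of 19363 tested, deposited ratios) to 3321 (of 38628, Cy5 alone). With single fish left out between 0 and 23 passed. No feature passed in limma without FO fish 4, 7 or 9 or without camelina fish 1, 3, 7 or 8, where 2756 to 3106 were at an unadjusted p under 0.05, while 23 passed without FO fish 5 and 22 without camelina fish 9.

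With loess normalization, features at an unadjusted limma p under 0.05 were more frequent than chance would give. With median centring in its place this was not shown. At an unadjusted limma p under 0.05 there were 2980 features, 1583 higher and 1397 lower on the camelina diet, where 1931 would be expected nominally without any difference. The other splits among 100 of the same fish, the real one included, gave a median of 1616 and at most 2841, so the range of chance is wide. With median centring in place of loess there were 1901 of the same 38628 features, which 33 of 100 splits of the fish reached, the real one included. With loess, 839 features were at an unadjusted limma p under 0.01, against 386 expected nominally, and 130 at one under 0.001, against 38.6. Other splits were not counted at these levels, and at 0.05 they strayed widely from the nominal number. The estimated share of tested features without a diet difference was 0.910, from the same p-values with loess only. The median log2 difference over all tested features was 0.0046; the normalization centres each array, so a shift of all transcripts together would not be seen.

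**Figure D2:**
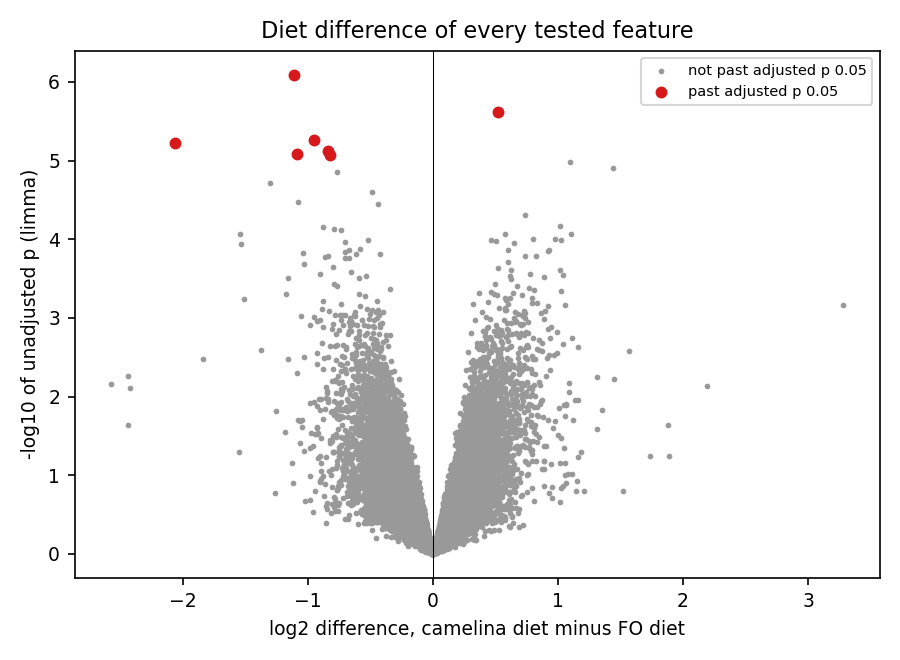
Each point is 1 of the 38628 tested features; the horizontal axis is the log2 difference, camelina diet minus FO diet, and the vertical axis is -log10 of the unadjusted limma p. The 7 features past an adjusted p of 0.05 are in red, 1 to the right of 0 and 6 to the left.

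The features at an unadjusted p under 0.05 were unevenly spread over the brightness of the array. The tested features were put into 5 equal classes by mean log2 intensity. Features at that level made up 0.893% of the dimmest class, and 5.23%, 9.85%, 11.8% and 10.9% of the following classes in rising order of brightness. Of features built from numbered contigs 8.88% were at that level (1002 higher and 841 lower on the camelina diet), of those built from numbered clusters 6.37% (569 higher and 546 lower), and of those built from GenBank or RefSeq records 6.08% (12 higher and 10 lower). These shares describe features, which are not independent replicates, and they were not tested.

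The diets were also compared over the 21052 features measured on all 18 arrays together. With loess normalization, the distance between the diet means was larger for the real diets than for any other of the 24310 splits of the fish into 9 and 9 (exact permutation p = 4.11e-05, the smallest these splits can give). Diet took up 8.37% of the variance between arrays, where 5.88% would be expected for a random split, and slide took up 26.9%, where 23.5% would be expected. With slide means removed and the diets exchanged only within slides, the distance was again the largest of 1296 splits (exact permutation p = 0.000772, the smallest these splits can give).

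Each fish was also compared with the mean of its own diet, computed without it, and with the mean of the other diet. With loess normalization, all 18 fish were nearer their own diet, 9 of 9 on the FO diet and 9 of 9 on the camelina diet. The exact permutation p was 4.11e-05, with at most 17 fish in the other splits. This comparison was not repeated with median centring or with slide taken into account. It uses the same ratios and diet means as the distance, so it is not separate support. The margin was narrow for camelina fish 1 and 9, whose scores toward the camelina mean were 0.000435 and 0.000676 in squared log2 units per feature, and wide for FO fish 7, at -0.0422. With median centring in place of loess the distance between the diet means had an exact permutation p of 0.164. With the Cy5 channel alone it was 0.000658, and with the deposited ratios 4.11e-05.

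**Figure D3:**
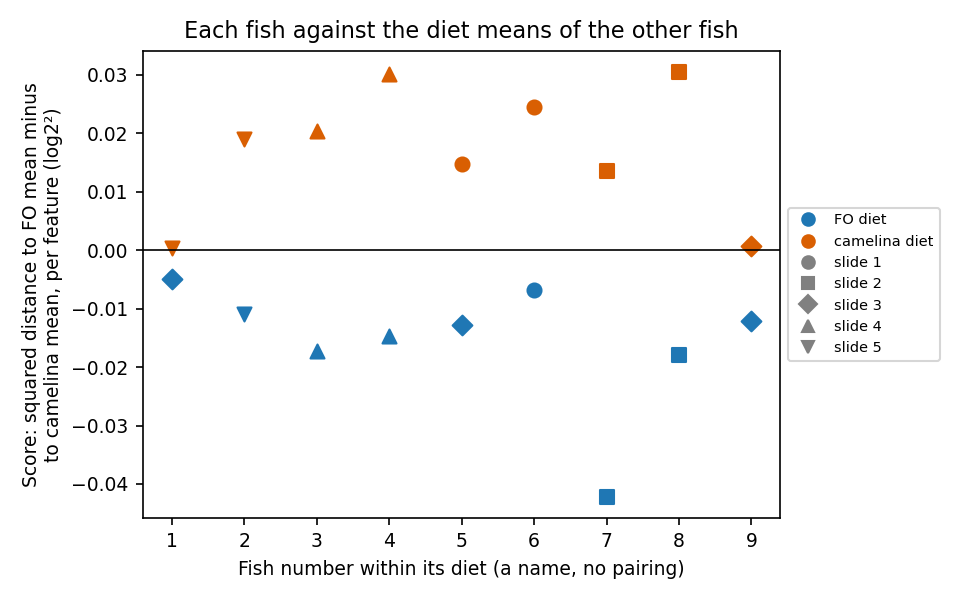
Score of each fish, the squared distance to the FO mean minus that to the camelina mean per feature (log2 squared), with the fish left out of its own mean; colours give the diet, marker shapes the slide, and the horizontal axis only numbers the fish of a diet. With loess normalization, all FO fish lie below 0, down to -0.0422, and all camelina fish above 0, with camelina fish 1 and 9 next to it.

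No feature was above background on every array of one diet and on no array of the other, in either direction. On 8 or more FO arrays and 1 or fewer camelina arrays 4 features were above background, and 0 the other way round, a difference that was not tested. Of the features on the array, 13142 were above background on all 18 arrays and 381 on none.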

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

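The test on the reference channel, the splits with median centring, the test on the spots around a spot, the wider set of FO fish 2 and the choice of the fish weighed here came after the results had been seen. The values of 22 groups of 9 fish were screened for a fish that stood apart from the rest of its diet, and chance would give about 1 in 20 groups. There were 4 such values. The score of FO fish 7 was -0.0422, where the other FO fish lay between -0.0179 and -0.0049. The median Cy5 intensity of FO fish 3 was 647, where the other FO arrays lay between 187 and 401. The other values that stood apart are numbers of features that were high in 1 fish alone.

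The difference between the diets was weighed against chance, slides and the reference channel. In 1 of 100 splits of the 18 fish, the real one, 7 features passed the adjusted threshold, and the highest of the other splits gave 2. The 2980 features at an unadjusted p under 0.05 were likewise reached by 1 of 100 splits, the real one, but another split gave 2841. Both counts argue against a chance split of the fish, the unadjusted one by a small margin. These splits do not take slide into account: with slide as a fixed block 1 feature passed, none of the 7, and 7 of the 18 removals of a single fish left 0. With median centring in place of loess, 33 of 100 splits gave as many features at an unadjusted p under 0.05 as the 1901 of the diets, so chance is not excluded there. Another of these splits gave 5043, where the median of the other splits was 1522. What sets that split apart was not tested. The exact permutation p of 0.000772 within slides opposes slides as the whole cause of the distance between the diet means. The image names also number the images of a slide, and the exchange within slides did not hold the image constant. Later images than image 1 gave the arrays of FO fish 1, 2, 3 and 4 and of camelina fish 3 and 6. The part of the image in the distance was not tested and stays open. For the 7 features, a median of -16.0% of the ratio difference lay in Cy3, with a range of -54.4% to 14.3%. These channel values were not scaled between arrays. The median of the arrays' median Cy3 was 254.5 for FO and 189.5 for camelina. A lower Cy3 on camelina arrays lowers this share for the 6 features that fell, so the share cannot settle the part of the reference. With Cy5 alone, scaled between arrays, all 7 kept their direction and 0 passed. The role of the normalization stays open. With median centring in place of loess the exact permutation p of the distance was 0.164. Without background subtraction and offset it was 0.00284. It was 0.000658 with Cy5 alone, 0.000452 with scale normalization and 4.11e-05 with the deposited ratios. An effect of diet remains as a hypothesis, and differences between tanks, each of which received 1 diet, stay open because the labels do not place the fish in tanks.

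Features high in 1 fish alone, at least 2 above the next highest of the other fish on the log2 scale, numbered 33 in FO fish 2, where the other FO fish had 0 to 16, and 27 in camelina fish 6, where the other camelina fish had 0 to 9. The 27 features of camelina fish 6 lay close together on the array, with a median of 4.12 spots to the nearest other one, below the 13.6 that random sets of spots reach at their 2.5th percentile. The spots around 11 of them were raised as well, where 0.675 would be expected, so a defect on the array surface may account for part of this set. For FO fish 2 the median distance was 19.1 spots, within the random range of 13.0 to 23.7, but the spots around 12 of its 33 features were raised, where 0.825 would be expected. A wider set of 61 features that varied together and were high in FO fish 2 lay at a median of 9.06 spots, below the 10.2 of random sets. The median distance misses defects of 1 to a few spots, so a defect may account for part of this set and cannot be assigned to all of it. The share of the gap in a lower Cy3 opposes a dim reference on the array. It was -2.40% for FO fish 2 and -4.70% for camelina fish 6. These channel values were not scaled between arrays either. The median Cy3 of the arrays was 285 and 242, within the 143.5 to 537 of all arrays. The gaps were a median of 8.8-fold and 7.5-fold. No biological explanation was tested for these sets.

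FO fish 1 had 16 such features, a median of 13.9-fold above the other fish. Their median distance was 35.0 spots, within the random range of 16.1 to 38.6, the surroundings of 2 were raised where 0.4 would be expected, and 7.56% of the gap lay in a lower Cy3. The last value, from channels not scaled between arrays, argues against a dim reference as the cause. As for FO fish 2, the distance misses small defects, so a surface defect stays open. The arrays of FO fish 1, FO fish 2 and camelina fish 6 came from images numbered 2, 3 and 2 of their slides, where most arrays came from image 1. FO fish 3, FO fish 4 and camelina fish 3 also came from later images and had 4, 7 and 9 such features. Whether the image plays a part was not tested. Transcripts particular to FO fish 1 remain a hypothesis, for which the design gives no test.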

How the results depend on the processing

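The filter on negative controls, the keeping of flagged spots, the limit on missing arrays and the removal of 3 arrays were chosen after seeing the data. The 7 features past the threshold in limma became 0 without background subtraction and offset (2685 at an unadjusted p under 0.05). There were also 0 with the Cy5 channel alone (3321) and with day as a block (3015). No feature passed with a filter of 14 arrays above background (2606 of 32379 tested) or with the deposited log ratios (2032 of 19363). That filter tested only 5 of the 7, without C079R110 and C113R049, and the deposited ratios tested 6. There was 1 with normexp offset 10, 1 without a filter on dim features, 1 with slide as a fixed block, 2 with scale normalization between arrays (1 higher, 1 lower, against 1 higher and 6 lower as reported), 4 with median centring without loess (1 higher, 3 lower), 3 without FO 1, FO 2 and camelina 6, and 14 at an adjusted p under 0.10. Rank products gave 456 (223 higher, 233 lower, 6 of the 7 among them), from a null that shuffles features within arrays, which gives noisy features no allowance. A random slide block (9), array weights (9), trended and robust eBayes (10), kept flagged spots (7) and at most 4 missing arrays (9) kept all 7. The filter on negative controls gave 8, with 5 of the 6 it tested among them. There C186R092 did not pass, at a limma adjusted p of 0.0695. Aquantile leaves log ratios unchanged and is not counted. In all these limma fits the measured members of the 7 kept their direction.

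Leaving out 1 fish gave 0 to 23 features: 0 without FO 4, 7 or 9 or camelina 1, 3, 7 or 8 (2756 to 3106 at an unadjusted p under 0.05), 1 without FO 2 or 3, 2 without camelina 4 or 5, 3 without FO 1, FO 8 or camelina 6, 4 without FO 6, 6 without camelina 2, 22 without camelina 9 and 23 without FO 5. The count at an unadjusted p under 0.05 fell to 1901 with median centring without loess, which 33 of 100 splits of the fish reached (median of the others 1522; 1616 as reported); otherwise it lay between 2032 (of 19363 tested) and 3321 (of 38628). The exact permutation p of the distance rose to 0.164 with median centring without loess, and otherwise stayed at or under 0.00391; leaving out 1 fish gave 4.11e-05 to 0.000329. The cause was not tested.

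C079R110 stayed past the threshold under 11 of 17 alternatives (limma adjusted p 0.0193 to 0.291), C113R049 under 7 of 17 (0.00775 to 0.438; log2 difference -5.85 without background subtraction) and C186R092 under 6 of 18 (0.0297 to 0.721), and C230R050 passed under 5 of 18 (0.0374 to 0.260). Directions did not reverse. With fish number as a replicate block 2 features passed, 3227 were at an unadjusted p under 0.05 and the exact permutation p of the distance was 0.00391, the smallest it can be. Same-numbered fish correlated in their deviations by -0.041 to 0.133, 2 of 9 pairs over 0.1 and 7 over 0 (median of other pairs -0.014); 7 of the 9 pairs shared a slide. Only the fish numbered 3 and those numbered 4 correlated best with each other across the diets, and the fish were not treated as paired. Gene lists, with camera, fry and means per gene, were not run, as features have no gene names here. Of the dimmest features 0.893% were at an unadjusted p under 0.05; whether low signal, the offset or small spread set this is open.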

Other observations

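All tests in this part were chosen after the data had been examined. The 1500 most variable features measured on all arrays were grouped by their correlation across fish, without regard to diet, which gave 21 groups of at least 10 features with an average correlation of 0.6 or more at the last merge. A group of 22 features was higher on the camelina diet. Its mean log2 ratio was -0.54 ± 0.47 (SD, n = 9) in FO fish and 0.30 ± 0.42 (SD, n = 9) in camelina fish, a difference of 0.84, with an exact permutation p of 0.00123 and an adjusted p of 0.0259 over the 21 groups. All 9 FO fish lay below 0 and 8 of 9 camelina fish above it. Its members vary together by construction, so they add no support to the group's mean, and 0 of them passed the adjusted threshold in limma. Under 5 other scalings and with the deposited ratios the difference lay between 0.75 and 1.08, with exact permutation p-values of 0.0121 to 0.0467 after adjustment over the 21 groups. Without single fish the adjusted exact permutation p was under 0.05 in 17 of 18 runs. It was 0.0536 without camelina fish 2 and fell to 0.00173 without camelina fish 9. Within slides the difference was 0.38, 0.88, -0.02, 0.86 and 1.55 on slides 1 to 5, so it was absent on slide 3, where the only camelina fish was fish 9. The features did not lie close together on the array, at a median of 23.0 spots against 15.0 at the 2.5th percentile of random sets.

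No other group passed. The next, of 12 features, was lower on the camelina diet by a log2 difference of -1.18, with an adjusted exact permutation p of 0.0749. Of the 21 groups, 8 with 216 features in all took over 50% of their range from 1 fish that stood apart. The largest of them held 61 features, with a mean log2 ratio of 2.92 in FO fish 2. The features of 3 groups lay closer together than at the 2.5th percentile of random sets: the 61 of FO fish 2 (9.06 spots against 10.2), 46 that were high in camelina fish 6 (4.12 against 11.4) and 19 that varied across fish of both diets (12.6 against 14.3).

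Whether the diet changed how much fish differ from each other was tested. The median ratio of variances, camelina over FO, was 0.938 over the 21052 features measured on all arrays, inside the range of 0.837 to 1.20 that holds 95% of all splits of the fish, so a general change in spread was not found.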
